A study of Mus musculus with 2 samples.

How the data were processed

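MicroRNA-seq was measured in 2 libraries of tissue labelled as a layer of the hippocampus, from adult male mice whose strain label is 5xFAD/CAST, aged 8 to 10 months. MicroRNA-seq sequences small RNA, with a size range of under 30 per the labels, which give no unit, and each read stands for 1 sequenced fragment. The labels number the libraries as biological replicates 1 and 2 of 1 group. They give a separate tissue record for each and a single shared donor record, so the labels do not settle whether the 2 tissues came from separate animals. No p-value here measures variation between animals. The tests between the libraries describe these 2 libraries only, whose spread may be technical, and the permutation tests take genes or clusters as their units. No control group or other strain was analysed here, so no effect of genotype or age was tested.

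The authors deposited raw read counts per microRNA gene for each library, in 3 columns: without regard to strand, on the strand of the gene and on the opposite strand. The assembly was mm10 with GENCODE release M21, per the text notes deposited with each library. The aligner, the counting tool and any read trimming are not given in the sources used here. Each table opens with 4 rows that name no gene: unmapped reads, reads that fit several places, reads at no microRNA gene and ambiguous reads. These rows held 64.8% of the reads of replicate 1 and 67.0% of those of replicate 2 and were left out of library sizes and tests. Reads that fit several places were 41.6% and 38.2% of all reads, and unmapped reads 16.6% and 22.6%. They carry no gene name. How reads of microRNAs with identical copies were shared between genes is not given in the sources used here, so genes with a copy are reported as uncertain. The counts hold no molecular identifiers, so intervals and floors cover counting error only.

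The column of reads on the strand of the gene was used. Of the reads in the opposite-strand column, all but 125 in replicate 1 and 65 in replicate 2 lay at genes that overlap another microRNA gene on the other strand. All 2202 gene IDs of the tables were found in GENCODE M21, which gave symbols, mm10 coordinates and the genes around each hairpin. Hairpin sequences came from the M21 transcripts. A gene was called shared if its hairpin held a stretch of 20 bases that also occurs, on either strand, in a microRNA gene at another place. This held for 1087 genes. Sequence shared between overlapping genes was not counted. Copies outside annotated microRNA genes were not searched, since no genome sequence was used here. Counts are per hairpin gene, so the 5′ and 3′ arms of a hairpin cannot be told apart.

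Abundance was computed as CPM, with the reads assigned to microRNA genes as the library size, and as percent of assigned reads, with the mean and SD of 2 libraries and exact Clopper-Pearson 95% intervals per library. A gene was called detected with at least 10 reads in both libraries. Depth was 3421977 assigned reads in replicate 1 and 2820468 in replicate 2, so a count of 0 allows up to 0.877 and 1.06 CPM (3 reads). Correlations used log2(CPM + 1) across detected genes, which are not independent replicates. The spread between libraries was estimated as the common biological coefficient of variation in edgeR 4.0.16 (R 4.3.3) with an intercept-only design. With 1 group there was no contrast for a quasi-likelihood test. Each detected gene's 2 counts were compared by a two-sided exact binomial test against TMM-scaled library sizes, with Benjamini-Hochberg adjustment over detected genes and a threshold of 0.05. This test asks whether 2 libraries differ beyond counting error. Log2 ratios are replicate 2 over replicate 1, on TMM-scaled counts without a pseudocount, with exact 95% intervals from the counts.

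A set of 17 gene lists was written before the data were examined: neuron-enriched, activity-regulated, astrocyte-rich, oligodendrocyte, microglia and leukocyte, endothelial and mural, erythroid, choroid plexus and ependyma, striated muscle and liver, embryonic stem cell, Hox cluster, miR-200 and miR-183 clusters, let-7 and miR-98, miR-17 to miR-92 family clusters, Dlk1-Dio3 imprinted region, Sfmbt2 cluster, and Alzheimer-linked. Lists overlap, and many members are expressed in several cell types. For lists with at least 3 detected members, the median abundance of the detected members alone was placed among 10000 random lists of the same size drawn from detected genes. The median log2 ratio was placed among 10000 random lists matched on 10 bins of mean expression. These percentiles describe 2 libraries and are not p-values. Shared and other genes were compared by a two-sided permutation test over genes (100000 resamples), as was the within-cluster SD of genes on 1 strand within 10 kb of a neighbour. The tests were run on simulated data with known answers. In Poisson counts drawn for the comparison of the libraries, the binomial test called 2 of 187 unchanged genes among 372 genes tested. It called 37 of 50 genes at the smallest fold simulated, 33 of 48 changed 1.5-fold, 43 of 46 changed 2-fold and all 41 changed 4-fold. The simulated counts held no spread beyond counting error and were tested against totals without scaling. They do not show how many genes would be called between like libraries with a wider spread.

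The rule for named genes, fixed before the data were examined, took the 20 genes with the highest mean CPM, the 3 most abundant detected members of each list, and the 5 largest log2 ratios in each direction among called genes with at least 100 reads in both libraries. The alternatives were other minimum counts, library totals or DESeq2 1.42.0 size factors in place of TMM, other pseudocounts, stretches of 18 or 22 bases, gaps of 3 or 50 kb, the count column without regard to strand, lists without shared members, an edgeR exact test and leaving out each library. A lowess correction for hairpin GC content and the removal of shared genes from the counts were added after seeing the data. Python 3.11.15, scipy 1.17.1 and statsmodels 0.14.6 were used.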

Results

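Small RNA was profiled in hippocampal tissue of adult male mice labelled 5xFAD/CAST. 5xFAD is a transgenic mouse model of Alzheimer disease, and CAST is a wild-derived mouse strain. The design held 1 group of 2 libraries and no control. The data show which microRNA genes received assigned reads, in what proportions of those reads, and how far the 2 libraries differed. Reads that fit several places carry no gene name, so ranks and shares hold among assigned reads only. Replicate 1 held 9713924 reads, of which 3421977 (35.2%) were assigned to a microRNA gene, and replicate 2 held 8551453 reads, of which 2820468 (33.0%) were assigned. Of the 2202 annotated microRNA genes, 389 were detected with at least 10 reads in both libraries, and these took 99.96% of the assigned reads in each. No read was assigned to 1446 genes in either library.

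The let-7 family dominated the assigned reads. These microRNAs are known for their role in the timing of development and are abundant in mature brain. The 12 measured genes of the let-7 and miR-98 list were all detected and together took 34.5% ± 1.58 of assigned reads (SD, n = 2). Mirlet7b (ENSMUSG00000065564.1; mm10 chromosome 15, 85707319 to 85707403, in an exon of the noncoding transcript Lncppara) was the most abundant gene, with 116781 ± 1924 CPM. Its share was 11.8% in replicate 1 (exact 95% interval 11.78 to 11.85) and 11.5% in replicate 2 (11.50 to 11.58). Mirlet7g (chromosome 9, 106178840 to 106178927, in an intron of Wdr82) had 104157 ± 16560 CPM and Mirlet7i (chromosome 10, 122985640 to 122985724, outside other annotated genes) had 50310 ± 5778 CPM. Mirlet7d and Mirlet7e had 35269 ± 12809 and 28537 ± 3852 CPM. The 6 members that share sequence with another gene added under 1 percentage point to the family's share, which was 35.1% in replicate 1 and 32.8% in replicate 2 without them. These copies of let-7a, let-7c and let-7f are uncertain, since reads that fit several places carry no gene name. Their small part therefore does not show that these microRNAs were scarce in the tissue.

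By assigned reads, Mir139 and Mir744 were the most abundant genes outside the let-7 family, and neither shares sequence with another microRNA gene. Mir139 (chromosome 7, 101475376 to 101475443, in an intron of Pde2a) had 93729 ± 7779 CPM, and Mir744 (chromosome 11, 65734733 to 65734832, in an intron of Map2k4) had 90534 ± 6151 CPM. Mir99a had 21593 ± 1129 CPM. Mir328, Mir151, Mir330 and Mir652 lay between 11410 and 14140 CPM. The 10 most abundant genes took 59.4% ± 0.73 of assigned reads, the first 20 took 71.7% ± 0.96, and the first 100 took 96.1% ± 0.22. Among the first 20, the SD of CPM between libraries was smallest relative to the mean for Mirlet7b, followed by Mir433 (14517 ± 251 CPM), and largest for Mir26b (10885 ± 4328 CPM). The order of the closest genes depends on the scaling. On TMM-scaled counts the log2 ratio was -0.13 for Mirlet7b, against 0.040 for Mir744 and -0.064 for Mir433.

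**Figure D1:**
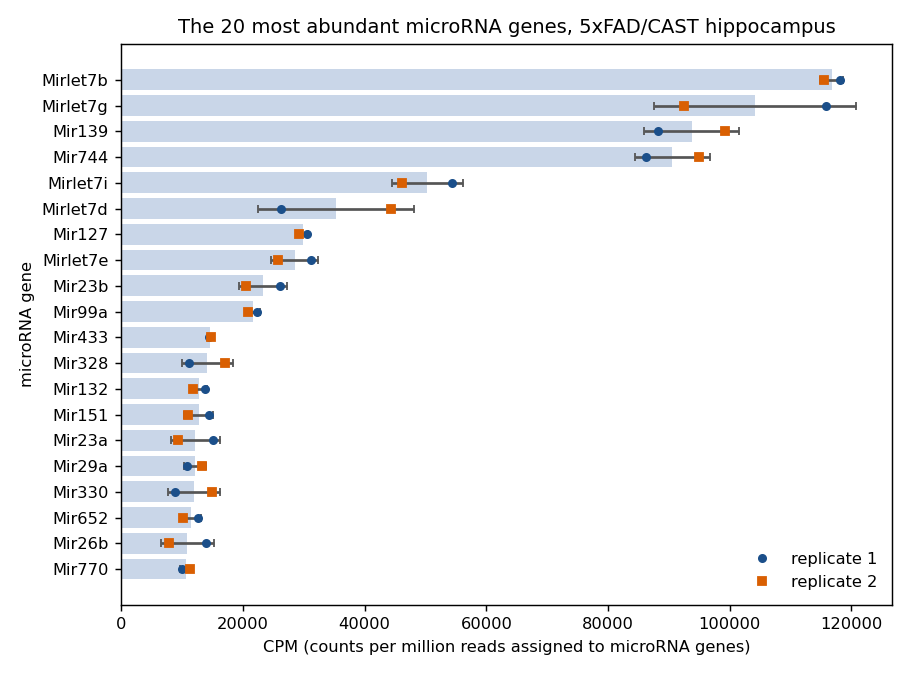
Abundance of the 20 microRNA genes with the highest mean, in CPM (horizontal axis). Bars are means of the 2 libraries, error bars are SD, circles are replicate 1 and squares replicate 2; Mirlet7b leads at 116781 CPM and 5 of the first 8 genes belong to the let-7 family.

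The microRNAs of the Dlk1-Dio3 imprinted region held the second largest share among the 17 gene lists. The noncoding RNAs of this region on chromosome 12, a large brain-expressed microRNA cluster among them, are known to be expressed from the maternal chromosome. Of the 58 measured genes on its list, 49 were detected, between positions 109563692 and 109747960, and together they took 9.87% ± 0.46 of assigned reads. The list goes by symbol and leaves out some genes of the region, Mir300 and Gm27379 among them. The median abundance of the 49 detected genes lay at percentile 99.6 of random lists of the same size. Mir127 (29871 ± 841 CPM) and Mir433 both lie opposite an exon of Rtl1, the paternally expressed gene that these microRNAs are known to target. Mir770 (10597 ± 972 CPM) lies in an exon of Meg3.

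Lists of brain cell types were present in unequal shares. The neuron-enriched list took 3.55% ± 0.12 of assigned reads, with 13 of 16 members detected. The median abundance of these 13 lay at percentile 97.1 of random lists. Of the detected members 8 share sequence with another gene, and the others held 2.02%. Mir132, an activity-regulated microRNA with a CREB-responsive promoter, led it with 12751 ± 1353 CPM, followed by Mir128-1 (7201 ± 219 CPM, shared sequence and so uncertain) and Mir137 (6409 ± 598 CPM). The 7 activity-regulated genes were all detected and took 1.68% ± 0.033, with Mir485 at 2361 ± 619 and Mir381 at 574 ± 325 CPM after Mir132. The astrocyte-rich list took 5.96% ± 1.06, led by Mir23b (23271 ± 3941 CPM) and Mir23a (12181 ± 4031 CPM), which share sequence with another gene, and Mir29a (12085 ± 1785 CPM). Of its 9 detected members 7 share sequence, and the others held 2.30%. Its members are also expressed by neurons and other cells, so the shares of the lists do not give a ratio of cells. The oligodendrocyte list took 0.585% ± 0.12 through Mir338 (3025 ± 1379 CPM, in an intron of Aatk) and Mir219a-2 (2819 ± 223 CPM), both known to promote myelination; Mir219a-2 shares sequence and is uncertain.

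Microglia, leukocyte, vascular and choroid plexus microRNAs were also detected. The microglia and leukocyte list took 0.485% ± 0.051, with 7 of 9 members detected. Mir342 had 2370 ± 22.1 CPM, Mir146, a feedback regulator of innate immune signalling, had 1076 ± 79.4 CPM (uncertain, as it shares sequence), and Mir150 had 924 ± 292 CPM. The endothelial and mural list took 1.74% ± 0.60. Mir143, a smooth muscle and pericyte microRNA, had 9132 ± 5174 CPM, Mir126a, in an exon of the endothelial gene Egfl7, had 7667 ± 287 CPM, and Mir145a had 614 ± 558 CPM. The choroid plexus and ependyma list took 0.253% ± 0.13, led by Mir34c (1397 ± 916 CPM) and Mir204 (985 ± 348 CPM), with Mir211 at 74.8 ± 2.04 CPM. The Alzheimer-linked list, chosen from general knowledge and not from these libraries, took 5.00% ± 0.57 with 22 of 25 members detected, led by Mir328 (14140 ± 4206 CPM), Mir132 and Mir29a. Without a control these levels are not a comparison with disease-free tissue.

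Lists of microRNAs typical of muscle, liver, red blood cells and Hox clusters each took a smaller share than the neuron, astrocyte, oligodendrocyte, microglia and vascular lists. The striated muscle and liver list took 0.0068% ± 0.00033, with Mir122 at 33.2 ± 3.62, Mir206 at 17.4 ± 3.98 and Mir499 at 9.94 ± 4.54 CPM. The muscle genes Mir1a-1, Mir133a-2 and Mir133b had 0 reads, but each shares sequence with a copy. The erythroid list took 0.0054% ± 0.00087, with Mir451a, the main microRNA of red blood cells, at 27.5 ± 8.28 CPM, Mir486 at 20.2 ± 0.49 and Mir144 at 6.08 ± 0.077 CPM. Mir486 overlaps Mir3107 on the other strand, and any sequence shared with it was not counted, so its level is less certain. The Hox cluster list took 0.0178% ± 0.0073, with Mir10a at 126 ± 39.7, Mir10b at 43.9 ± 30.0 and Mir615 at 4.29 ± 0.55 CPM. The miR-17 to miR-92 family clusters took 0.302% ± 0.0065, with 9 of 15 genes detected, led by Mir93 (1282 ± 90.1 CPM), Mir17 (598 ± 122 CPM) and Mir92-1 (399 ± 130 CPM, shared). The list named after the Sfmbt2 cluster, a rodent-specific array of repeated hairpins, had 8 of 81 genes detected and took 0.125% ± 0.021. It was led by Mir467d, Mir669c and Mir467e (458 ± 11.4, 391 ± 79.9 and 227 ± 67.9 CPM). Of the 81 genes on the list, 79 share sequence with a copy. The list goes by symbol, so it leaves out some genes of the cluster, such as Gm22072. It also holds some, such as Mir467f, that are not joined to that cluster.

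Genes with a copy elsewhere were counted lower than genes without one. Of 1087 genes that share 20 bases with another microRNA gene, 81 (7.45%) were detected, against 308 of 1115 (27.6%) of the others. The mean log2(CPM + 1) was 0.59 (SD 2.09 over genes) for shared genes and 2.24 (SD 3.61) for the others, a difference of -1.65 (two-sided permutation test over genes, p = 1e-05, the smallest that the resamples can give). The test takes genes as independent units, but copies are not, and 117 of the shared genes lie in 1 cluster on chromosome 2. Its p therefore overstates the evidence. Among detected genes alone, a set from which the minimum count had removed the low genes, the difference was 0.18 (permutation p = 0.67). The brain microRNA miR-124 is encoded by 3 copies. Mir124a-1 had 5 reads in each library and Mir124a-2 and Mir124a-3 had none. Mir9-1, Mir9-2 and Mir9-3, the copies of a neural microRNA, had 63, 7 and 214 reads in replicate 1. The miR-124 and Mir9 genes were singled out after their values were seen. Reads that fit several places, which carry no gene, outnumbered all assigned reads, at 4037293 and 3264159.

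Detected genes near each other on 1 strand had closer abundances than genes drawn at random. The 148 detected genes in 42 clusters, joined where neighbours lay within 10 kb, had a mean within-cluster SD of 2.34 on the log2(CPM + 1) scale, against 2.91 with the values shuffled (two-sided permutation test over genes, p = 0.031). With a pseudocount of 10 CPM the p was 0.092, and with the count column that disregards strand it was 0.086.

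The 2 libraries ranked the microRNAs alike but differed in level beyond counting error. Across the 389 detected genes, which are not independent replicates, Pearson's r of log2(CPM + 1) was 0.967 and Spearman's rho 0.958. The common biological coefficient of variation was 0.41 (edgeR). Over the 241 genes with at least 100 reads in both libraries, the SD of the log2 ratio was 0.80, against 0.083 in Poisson counts simulated at the same depth. By the exact binomial test with Benjamini-Hochberg adjustment, 263 of 389 genes differed, 132 higher and 131 lower in replicate 2, and 87 of these differed at least 2-fold. This test compares the 2 libraries, not conditions. The edgeR exact test takes its error from the same 2 libraries, so that error includes the difference under test. With the spread of both libraries as the error (edgeR exact test), 2 genes passed, Mir183 (adjusted p = 0.016) and Mir26a-1 (adjusted p = 0.0039), and 23 had an unadjusted p under 0.05.

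**Figure D2:**
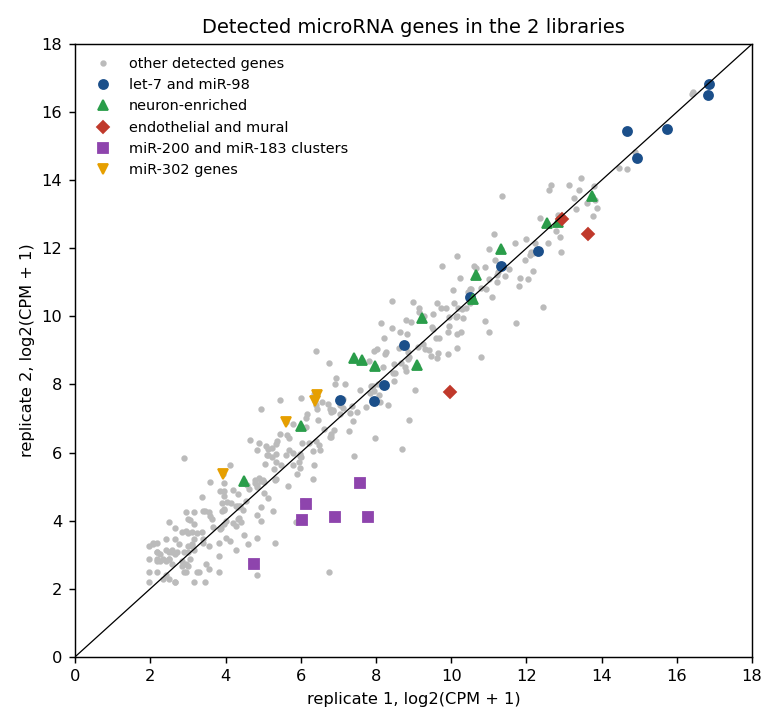
Each detected microRNA gene in replicate 1 (horizontal) against replicate 2 (vertical), on the log2(CPM + 1) scale, with the line of equality. Most genes follow the line (Pearson's r 0.967), the 6 detected genes of the miR-200 and miR-183 clusters lie below it and the 4 miR-302 genes above it.

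Among called genes with at least 100 reads in both libraries, the 5 furthest apart in each direction were named by the fixed rule. Larger ratios occurred at genes with fewer reads in a library, Mir26a-1 (shared sequence and so uncertain) and Mir183 among them. In replicate 1, Mir380 was 6.44-fold higher (log2 ratio -2.69, 95% interval -2.91 to -2.47), Mir145a 4.91-fold, Mir674 4.84-fold, Mir376a 4.22-fold and Mir1298, in an intron of the serotonin receptor gene Htr2c, 4.11-fold. In replicate 2, Mir339 was 5.62-fold higher (log2 ratio 2.49, 2.31 to 2.68), mmu-mir-3535 4.85-fold, Mir149 4.25-fold, Mir377 4.09-fold and Mir497 3.82-fold. These intervals cover counting error in 2 libraries. The edgeR exact test takes its error from the same 2 libraries, so failing it does not show that a gene agreed between them. None of the 10 passed the edgeR exact test, where their adjusted p lay between 0.26 and 0.54. Mir380, Mir376a and Mir377 all belong to the Dlk1-Dio3 region and differed in opposite directions.

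The medians of 5 of the 16 lists placed lay outside the middle 95% of matched random lists, a range that some random lists also leave by construction. The matched lists draw genes singly, so cluster neighbours within a list do not count as separate evidence. Unmapped reads also differed between the libraries, at 16.6% in replicate 1 and 22.6% in replicate 2. The 6 detected members of the miR-200 and miR-183 clusters, microRNAs of epithelia and sensory organs, were all lower in replicate 2, with a median log2 ratio of -2.45 (percentile 0.01 of matched lists). Mir183 (chromosome 6, 30169668 to 30169737) had 748 and 46 reads, Mir200c had 653 and 95, and Mir182 had 406 and 46. The 3 detected endothelial and mural genes were all lower in replicate 2 (median -1.32, percentile 0.23), with log2 ratios of -1.32 for Mir143, -2.30 for Mir145a and -0.18 for Mir126a. Mir143 and Mir145a are neighbours within 1.43 kb on chromosome 18. The 4 detected genes of the embryonic stem cell list, all from the miR-302 cluster (chromosome 3, 127545228 to 127545689, opposite an intron of Larp7), were all higher in replicate 2 (median 1.19, percentile 99.2; 95.8 among genes with at least 100 reads). Mir302a, Mir302b and Mir302d had 146 ± 85.6, 131 ± 69.5 and 82.2 ± 49.3 CPM, of which Mir302a and Mir302b share sequence and are uncertain. The Sfmbt2 cluster (7 of 8 lower, median -0.62, percentile 1.44) and the astrocyte-rich list (5 lower, 3 higher, median -0.45, percentile 1.76) were the other 2. After a correction for GC content their medians were -0.34 (percentile 8.41) and -0.39 (percentile 3.42). The astrocyte-rich list lay at percentile 51.6 with at least 100 reads in both libraries; Mir26a-1 and Mir26a-2, its members furthest from 0, had 13 and 41 reads in replicate 2, share sequence, and were named after their values were seen.

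The other lists stayed within the range of matched lists. In the neuron-enriched list, 9 members were higher and 4 lower in replicate 2 (median 0.48, percentile 97.0; 98.2 after the GC correction). Both copies of Mir138, Mir129 and Mir218 were among the higher genes and both copies of Mir128 among the lower. Copies share sequence and do not count as separate evidence. Of the choroid plexus and ependyma list, 3 were lower and 1 higher (median -0.60, percentile 5.25), of the Hox cluster list 2 of 3 lower (-0.76, percentile 3.58), and of the microglia and leukocyte list 5 of 7 lower (-0.25, percentile 16.6). The let-7 and miR-98 list had 4 higher and 7 lower (-0.23, percentile 23.9) and the Dlk1-Dio3 region 19 higher and 23 lower (-0.14, percentile 20.9). The activity-regulated (0.34, 83.0), Alzheimer-linked (0.15, 84.0), miR-17 to miR-92 (0.11, 56.8), erythroid (-0.050, or 0.049 with library totals in place of TMM; 32.2) and striated muscle and liver (-0.22, 19.7) lists had the median log2 ratios and percentiles given. In the oligodendrocyte list, with 2 detected members, Mir338 was higher and Mir219a-2 lower in replicate 2. Adjusted over the list alone, the counts changed by 1 gene in 4 lists: 1 more lower gene in the astrocyte-rich, Dlk1-Dio3 and Alzheimer-linked lists, and no higher gene in the erythroid list in place of 1.

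**Figure D3:**
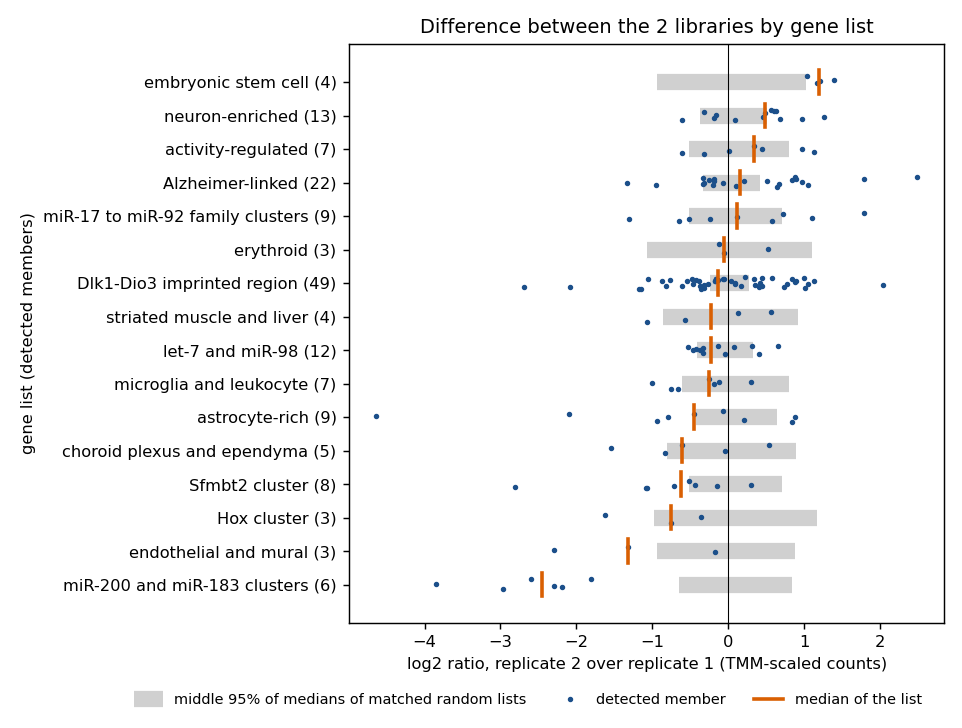
Log2 ratio of replicate 2 over replicate 1 (horizontal axis) for the detected members of 16 gene lists (rows, with the number of members). Points are genes, orange bars are list medians and grey bands hold the middle 95% of medians of expression-matched random lists; the median of the miR-200 and miR-183 clusters (-2.45) lies furthest from its band.

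Hairpin GC content, examined after the data were seen, was related to the difference between the libraries. Across the 389 detected genes, Spearman's rho between GC content and the log2 ratio was 0.27 and Pearson's r 0.24 (permutation over genes, p = 1e-05 for each, the smallest that the resamples can give). The median log2 ratio was 0.41 in genes with a GC content of at least 58.2% and -0.21 in genes with at most 45.2%. Removing this trend took away 6.62% of the variance of the log2 ratio.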

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

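Tests that weigh explanations were chosen after the results were seen, and no biological explanation from the design was tested, since it has 1 group. RNA from other cells was weighed as a technical explanation. Reads were present in parts of the tables that the comparisons did not use. Reads that fit several places were 41.56% of replicate 1 and 38.17% of replicate 2. Reads at no microRNA gene were 6.58% and 6.29%. Opposite-strand reads summed over the 2138 genes with no microRNA gene opposite numbered 125 and 65, or 0.00392% and 0.00246% of the reads counted there on either strand. The column that disregards strand held under 1% of the reads of 26 detected genes, each of which overlaps a microRNA gene on the other strand. Those 26 genes held 6.85% and 6.25% of assigned reads, Mirlet7e and Mir126a among them.

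MicroRNA genes with a copy elsewhere had few reads, miR-124 among them. Reads that fit several places stood in a row that names no gene. If their loss lowered the counts of shared genes, those genes should lie below unshared neighbours of the same cluster. Over 33 clusters holding both kinds, the median difference of shared from other genes was -0.82 on the log2(CPM + 1) scale. The mean was -1.87 (two-sided permutation of signs for the mean, p = 0.00142). Differences ran from -7.63 (Mir29b-1 against Mir29a) to 4.99 (Mir26a-2 against Mir546). A loss cannot show in clusters where both kinds had few reads, such as miR-290 to miR-295 (-0.039). The median and mean ran in the direction of such a loss, but the median fell short of the bound of -1 set for it. Clusters with few reads of both kinds entered the median and can hold it small. Falling short of the bound therefore does not argue against a loss. How far this loss explains the deficit therefore stays open. The median was -0.77 with an 18-base stretch and passed that bound only with a 22-base stretch, at -1.25. Low transcription of the places where shared genes lie would leave their neighbours as low. Shared genes were lower in 72.7% of the clusters (24 of 33, exact binomial p = 0.0135), under the bound of 75% set for excluding it. Clusters with few reads of both kinds entered this share as well, so it neither shows nor excludes a part of low transcription.

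The miR-200 and miR-183 cluster genes were lower together in replicate 2, at 3 places in the genome. The trend with hairpin GC content was small, with median log2 ratios of 0.41 in genes of high and -0.21 in genes of low GC content. Removing it could move the list's median little, which was -2.49 after the GC correction, against -2.45 before. This hairpin trend is therefore too small to be the whole cause. The GC content of the sequenced fragments was not examined. More choroid plexus or ependyma in replicate 1 may contribute, as that list's median log2 ratio was -0.60 (percentile 5.25). Mir34c (6997 and 2114 reads), Mir204 (4214 and 2084) and Mir34b (117 and 68) were lower in replicate 2. Mir211, at -0.043 (251 and 215 reads), and Mir449a, at 0.53 (109 and 139), were not. The 2 directions leave this explanation open. RNA from another tissue rich in these microRNAs, a difference between animals and a difference in library preparation were not tested and cannot be told apart from the replicate number.

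The miR-302 genes, of a cluster known from pluripotent cells, were counted in both libraries, with 784 and 1535 reads. Mir367, a gene of the same cluster outside the list, held no assigned reads. RNA of mouse embryonic stem cells, where the miR-290 to miR-295 genes are also abundant, is argued against: those 9 genes held 1 read, or 0.043% of the miR-302 reads. For the difference between libraries, the trend with hairpin GC content ran the other way. Mir302a, Mir302b and Mir302d have a GC content of 42.0%, 39.2% and 39.4%, and genes with at most 45.2% had a median log2 ratio of -0.21. That direction argues against the hairpin trend as the cause. The median log2 ratio was 1.41 after the correction and 1.19 before, but a trend this small could not have removed the difference. The GC content of the sequenced fragments was not examined here either. Low expression in the tissue and carry-over from other libraries stay open and were not tested.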

How the results depend on the processing

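Alternatives were fixed before the data were examined, except the GC correction and the removal of shared genes from the counts, which were added later. Detected genes numbered 607 with at least 1 read and 179 with at least 100 CPM in both libraries, against 389, and 410 and 424 in replicate 2 or replicate 1 alone. The share of the 10 most abundant genes was 55.7% with Mirlet7b left out and 62.1% in the column without regard to strand, and 58.9% to 59.9% in single libraries. Over all genes with at least 1 read, Pearson's r was 0.978 and Spearman's rho 0.926. The count of genes differing between libraries lay between 204 and 283 under 6 alternatives of the binomial test and was 2 by the edgeR exact test, whose error includes the difference itself. Without shared members, list shares were 2.02% (neuron-enriched), 2.30% (astrocyte-rich), 0.302% (oligodendrocyte), 0.377% (microglia and leukocyte) and 8.83% (Dlk1-Dio3). With Mirlet7b out of the total they were 4.01% (neuron-enriched), 0.549% (microglia and leukocyte), 25.8% (let-7 and miR-98) and 11.2% (Dlk1-Dio3). The let-7 and miR-98 value leaves Mirlet7b out of the list as well as out of the total. In the column without regard to strand they were 3.71% (neuron-enriched), 0% (oligodendrocyte) and 1.04% (endothelial and mural), where genes with an overlapping opposite microRNA gene lose their reads. Single libraries gave 3.46% to 3.63% (neuron-enriched), 5.22% to 6.71% (astrocyte-rich), 0.503% to 0.667% (oligodendrocyte), 0.449% to 0.521% (microglia and leukocyte), 1.32% to 2.17% (endothelial and mural), 33.4% to 35.6% (let-7 and miR-98) and 9.54% to 10.2% (Dlk1-Dio3). The neuron-enriched median log2 ratio moved outside the range of matched lists with the strand-blind column (0.45) and the GC correction (0.42). The astrocyte-rich median moved inside it with at least 100 reads (-0.068), with the strand-blind column (-0.48) and with the GC correction (-0.39). The embryonic stem cell list did so with at least 100 reads (1.18), and the Sfmbt2 cluster with at least 100 reads (-0.47) and the GC correction (-0.34); for these list shifts the cause was not tested. The mean difference of shared from other genes was 0.18 (permutation p = 0.673) over detected genes alone, where the minimum count removes the low genes, so that value does not bear on the deficit over all genes. It was -1.64 and -1.61 in single libraries. The cluster SD difference was no longer past the threshold with a pseudocount of 10 CPM (-0.41) or the strand-blind column (-0.50), and was -0.71 and -0.57 in single libraries. The opposite-strand share was 5.89% and 6.42% in single libraries. The shift of the miR-200 and miR-183 clusters stayed beyond the matched lists under the 4 alternatives tried. With 2 libraries, each single-library value lies equally far from the mean by construction, so the single-library values of abundance show no stability. No paired analysis was possible because there is 1 group. Depth limits statements on genes under about 10 reads, and reads that fit several places limit those on copies.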

Other observations

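Mir203, another epithelial microRNA, outside the fixed lists and picked after its values were seen, had 854 and 241 reads, a log2 ratio of -1.65. Mir26a-1 had 366 and 13 reads and Mir26a-2 had 199 and 41, while Mir26b, without shared sequence, had 47721 and 22069. In the cluster of chromosome 13, Mir23b had 89169 reads in replicate 1, Mir27b 4774 and Mir24-1 59; all of these genes share sequence with another microRNA gene.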
